A study of Drosophila melanogaster with 3 samples.

How the data were processed

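Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole prepupae of mixed sex from a transgenic Drosophila melanogaster line that carried CG32006 with GFP at its C-terminus, and an antibody against GFP was used for the pull-down. The labels describe 3 biological replicates of 1 group and no second condition. They give an age of 48 days, which is not the age of a prepupa, and the stage name was used here. Chromatin was sheared by sonication, per the labels. A control alignment is named in the deposited notes and was not analysed here. The aligner, the peak caller, the read depth and the cut-off on the irreproducible discovery rate (IDR) are not given in the sources used here.

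The authors deposited peak lists in the builds dm6 and dm3. For each replicate, a list of 30000 peaks and background regions had been called on that replicate against the control and served as input to the IDR comparison. A pooled list of 30000 peaks had been called on all 3 replicates together. The optimal list, which the authors named as thresholded by IDR, had 11665 rows in dm6 and 11625 in dm3. In both builds every row of the optimal list was also found in the pooled list. The optimal rows were exactly the pooled rows with the highest signal, so a row need not have recurred in each replicate. The optimal list was therefore made from the replicates' own reads, so that its overlap with their lists is not an independent check. Lists of 2 replicates came from different libraries, but each was called against a control, and a control in common would make their overlap not fully independent either. The peak signal values are the authors' deposited values, on a scale that the file headers do not state, and they were used only to rank and describe peaks within a list. The −log10 q values are as the authors deposited them. Pooled signal values have no replicate error. Depth is unknown, so intervals cover counting error of peaks or genes only.

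Coordinates are in dm6 and are printed counting from 1. The Release 6 genome sequence and the Ensembl gene annotation (release 115) use the same coordinates, and every dm6 peak lay within the length of its chromosome arm. A dm3 genome was not used here, so dm3 lists entered only counts and overlaps. The summit was the peak start plus the deposited offset, and 9 offsets of the optimal list that pointed past the peak end were set to its last base. In the optimal list, 240 rows repeated the coordinates of another row with a different summit, and each was kept. For replicate comparisons, each replicate's 11665 strongest peaks were taken (the N strongest), and an optimal peak counted as supported by a replicate when its summit lay inside such a peak. A summit was promoter-proximal within 500 bp of a transcription start site (TSS) of a protein-coding gene. The other locations were assigned in the order coding exon, 5' UTR, 3' UTR, intron, non-coding gene and intergenic.

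Shares have Wilson intervals at the 95% level. Promoter share and location were tested against 1000 shuffles of the summits within their arms (two-sided permutation test). Summits per arm were tested against arm length with exact binomial tests over 6 arms. Median signal was compared between promoter-proximal and other peaks by a two-sided permutation test with 100000 resamples. A gene was called bound when it had a promoter-proximal summit, and 30 gene lists were tested with Fisher's exact test against all protein-coding genes on the 6 arms. Of the list members, 3 entries had no unique match to a gene symbol and were left out. For 21 motifs and all 7-mers with at least 20 discordant pairs, windows reaching 50 bp either side of the summit were compared with a window of the same size centred 500 bp away on a randomly chosen side (exact McNemar test). Families of tests were adjusted by the Benjamini-Hochberg method. Peaks close to each other are not independent, so p-values over peaks describe these lists and not further animals. The spread over replicates is the SD of the values from the 3 replicate lists.

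Genes were named by a rule. It took CG32006, the genes at the 20 strongest optimal peaks supported by all 3 replicates, up to 4 bound members with the strongest promoter peak from each list that passed, all bound members of the ecdysone response and forkhead lists (up to 15 each), and the 5 most frequent 7-mers among those that were more frequent at summits. With the exceptions given below, the tests, lists, rule and main alternatives were fixed before the data were examined. Alternatives were other distances to the TSS, other overlap rules, the dm3 lists, the strongest 50% of peaks, each replicate's own list, peaks supported by both other replicates when 1 replicate was left out, windows of 100 bp either side, and dinucleotide-shuffled summit windows as the sequence control. The comparison of GC content, the location classes other than promoters, and the alternatives for these were the exceptions and count as added after the data were seen.

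The tests were checked on simulated data. With the real list sizes, 96.0% of 300 lists planted at a bound share of 60% were called by the gene list test, and 0.630% of 2700 unchanged lists. The planted lists had 23, 41 or 26 genes, so the share called was not simulated for smaller lists, nor for lower bound shares. All other genes had the same chance of being bound. False calls that arise from the number of TSSs per gene were therefore not covered. In random genome windows 0 of 8192 7-mers and 0 of 21 motifs were called, and all 20 planted 7-mers were recovered. Random windows have no systematic difference in base composition from their flanks. Calls that arise from the low GC content of the real summits were therefore not covered by this check. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1 were used.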

Results

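Binding of CG32006-GFP was mapped in whole prepupae. CG32006 lies on chromosome 4 (dm6, 150764 to 153538, plus strand), and the RefSeq gene table lists FoxJ1 among its synonyms, a name from the forkhead family of transcription factors. The data were 3 biological replicates. The optimal list held 11665 peaks with a median width of 470 bp, and signal values from 197 to 10303. Among the 30000 regions listed per replicate, 14910 in replicate 1, 9587 in replicate 2 and 17614 in replicate 3 had a −log10 q of at least 2. The dm3 list was of similar size, with 11625 peaks.

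The replicates shared most of their strong peaks. Between pairs of replicate lists of 11665 peaks, 83.0% of summits lay in a peak of the other list for replicates 1 and 2, 85.9% for replicates 1 and 3, and 79.6% for replicates 2 and 3. Shuffled optimal summits fell into a given replicate's list in 3.25% ± 0.216 (SD, n = 3) of cases. Of the optimal peaks, 8581 (73.6%, Wilson 95% interval 72.8 to 74.4%) were supported by all 3 replicates, 2242 by 2, 765 by 1 and 77 by 0. Each replicate supported 88.6% ± 0.961 (SD, n = 3) of them. Among 1000 sets of shuffled summits the mean share supported by all 3 was 1.91% and the highest was 2.34%. Support fell with signal, from 98.1% in the strongest 10% of the peaks to 10.9% in the weakest 10%. Because the optimal list came from the same reads, this support is not an independent test. The share rose to 90.5% with replicate lists of 2 times that length and was 56.9% when a reciprocal overlap of 50% was required.

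Of the 20 strongest peaks supported by all 3 replicates, 9 lay within 500 bp of a TSS, 8 in introns, 2 between genes and 1 in a non-coding gene. The strongest of all (chromosome 2L, 480427 to 481384, signal 10303) had its summit in an intron of ush, and the nearest TSS, 1392 bp away, was that of cbt, which encodes a zinc finger transcription factor. The promoter-proximal peaks belonged to CG14100 (chromosome 3L, 19590369 to 19590849, summit 91 bp from the TSS), Ugalt (35 bp), CG31145 (196 bp), PNPase (81 bp), Chro and Ssl1 (105 bp), Hsp27 (159 bp), larp (331 bp), CG18549 (111 bp), and CHMP2B and Tcs5 (102 bp). Hsp27 encodes a small heat shock protein and Chro a chromodomain protein. The intronic summits included those nearest to HmgZ (595 bp), which encodes a high mobility group protein, to Trl (1526 bp), which encodes the GAGA factor, and to osa (13945 bp), which encodes a subunit of a Brahma chromatin remodelling complex. The others in introns were nearest to CG11050 (1024 bp), CG4496 (561 bp), CG32772 (1274 bp) and CG16753 (5721 bp, inside CG32486). The intergenic summits lay 11924 bp from CG13323 and 7624 bp from RYBP, and that in a non-coding gene 5037 bp from CG4004.

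Introns and promoters held most of the summits, and coding exons held very few. Introns took 50.9% of the summits (replicate lists 50.2% ± 0.424, SD, n = 3) against 39.3% after shuffling, a ratio of 1.29. Promoters took 22.9% (24.2% ± 1.94, n = 3) against 11.5%, a ratio of 2.00. Only 29 summits, 0.249%, lay in coding exons outside promoters (0.231% ± 0.0562, n = 3), where shuffling placed 14.0%. In 3' UTRs the share was 0.746% against 4.53%, and between genes 22.1% against 27.9%. Each of these differences had a permutation p of 0.002, the smallest that 1000 two-sided shuffles can give, and an adjusted p of 0.0028. The shares in 5' UTRs (0.652% against 0.614%, permutation p = 0.625) and non-coding genes (2.43% against 2.18%, permutation p = 0.0779) did not pass. Background regions of the pooled list, ranked below the optimal peaks, had 50.8% of their summits in introns, 1.83% in coding exons, 1.17% in 3' UTRs and 12.7% in promoters. The intron share and most of the scarcity in coding exons and 3' UTRs were therefore not particular to the optimal peaks. Some of these regions may be enriched, since 13638 pooled rows had a −log10 q of at least 2, against 11665 optimal rows. The classes other than promoters were not part of the planned tests. The median distance from a summit to the nearest protein-coding TSS was 2618 bp.

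**Figure D1:**
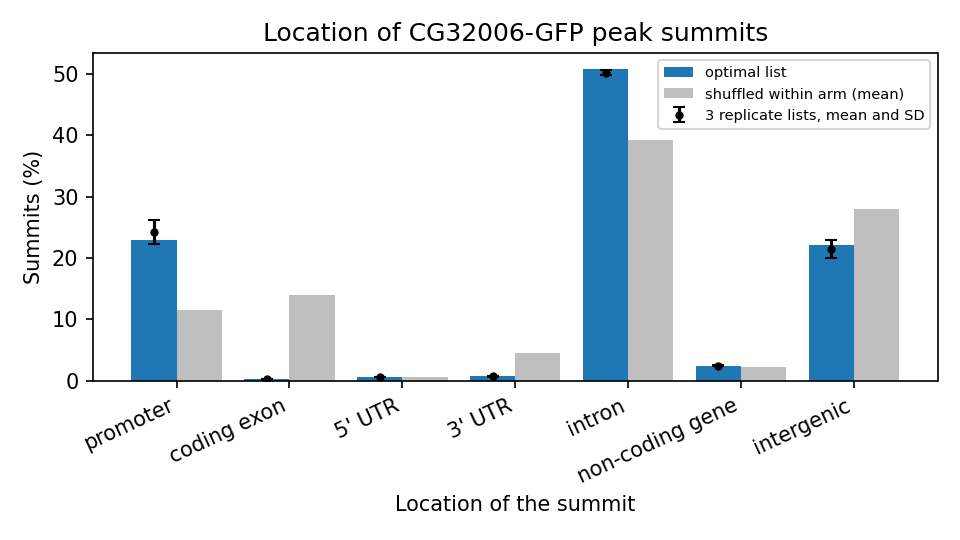
Share of optimal peak summits (percent, blue bars) in each class of location, with the mean of 1000 shuffles within arms (grey bars) and the mean and SD of the 3 replicate lists (black). Coding exons hold 0.249% of summits against 14.0% after shuffling.

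Promoter-proximal peaks were stronger than the rest. Their median signal in the optimal list was 541 (2676 peaks) against 421 for the 8989 others, a ratio of 1.28 (permutation p = 1e-05, the smallest that 100000 resamples can give). The promoter-proximal share was 41.0% in the strongest 10% of the peaks and 17.2% in the weakest 10%. Within each replicate's own list the ratio of medians was 1.19, 1.35 and 1.18 for replicates 1, 2 and 3.

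CG32006-GFP peaks were nearly absent from chromosome 4, which carries CG32006 itself. That chromosome had 4 summits where its length predicted 117, a ratio of 0.0341 (exact binomial adjusted p = 4.52e-44), and the ratio over replicate lists was 0.0795 ± 0.0554 (SD, n = 3). The 4 peaks lay 242 bp from a TSS of Sox102F, 163 bp from one of PlexA, in an intron 2367 bp from Sox102F, and 3403 bp from the TSS of ci, the gene of the Hedgehog pathway effector. Over CG32006 there were 0 optimal peaks, the nearest summit was 90320 bp away, and 0 regions of the pooled or replicate lists lay within 5 kb of it. Background regions of the pooled list were as scarce on chromosome 4 (2 of 18335, a ratio of 0.0108). The scarcity was therefore not particular to the optimal peaks and cannot be read as a lack of binding. On the X chromosome summits were denser than length predicts (2277 summits, ratio 1.11, exact binomial adjusted p = 9.28e-08), as they were on 3L (2717, ratio 1.11, exact binomial adjusted p = 3.60e-09). They were sparser on 2R (1911, ratio 0.867, exact binomial adjusted p = 6.25e-12) and slightly so on 3R (2673, ratio 0.956, exact binomial adjusted p = 0.00976), and on 2L the ratio was 1.02 (exact binomial adjusted p = 0.401). The 3R difference did not pass in the strongest 50% of peaks (ratio 0.970) or in the list of replicate 2 (0.973), and with genes per arm as the denominator 2L passed below 1 (0.937).

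**Figure D2:**
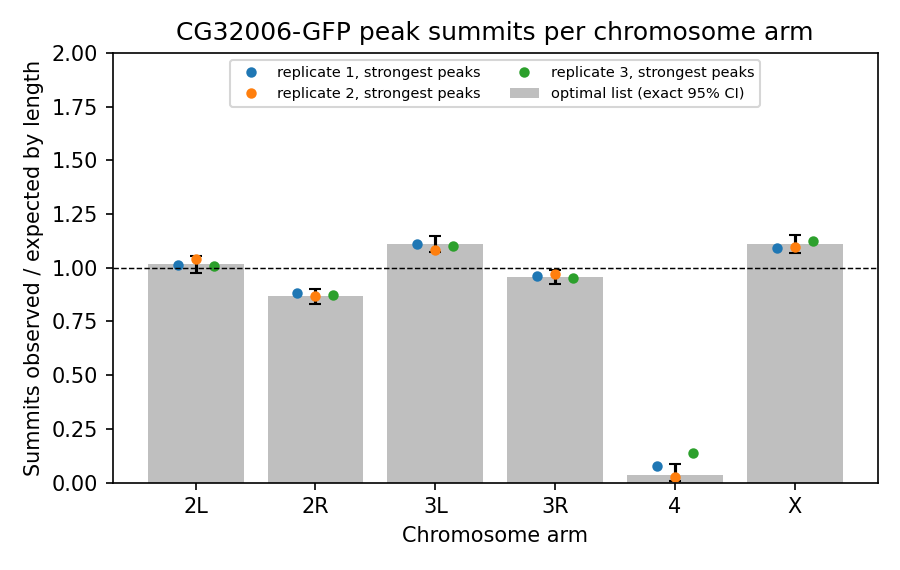
Observed over expected number of summits (by length) per chromosome arm for the optimal list (bars from 0, exact 95% interval) and for the strongest peaks of replicates 1, 2 and 3 (points). Chromosome 4 has a ratio of 0.0341 in the optimal list, and the other arms lie between 0.867 and 1.11.

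Genes of the ecdysone response, the fat body, the circadian clock, chromatin and the cytoplasmic ribosome were bound at their promoters more often than other genes, and genes for chemoreceptors, cuticle and the male accessory gland less often. Of 13945 protein-coding genes 2659 were bound (19.1%, replicate lists 20.2% ± 1.90, SD, n = 3). Of the 30 lists, 5 were higher and 3 lower than that background at an adjusted p under 0.05 by Fisher's exact test, two-sided. At a raw p under 0.05 there were 13 lists. Against genes with the same number of TSSs, a comparison added after the data were seen, the ecdysone (permutation adjusted p = 0.0523), circadian (0.132) and accessory gland (0.0562) lists did not pass, and the other 5 did.

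The ecdysone response list had 14 of its 23 genes bound (60.9%, 3.19-fold, Fisher's exact adjusted p = 8.72e-05), with 58.0% ± 9.05 (SD, n = 3) over the replicate lists. The strongest promoter peaks were at E23, an ecdysone-induced ABC transporter gene (signal 4975), and at Eip75B, a nuclear receptor gene (2920), followed by Eip63E (1250). Both genes of the ecdysone receptor were bound, EcR (973) and usp (632). So were Eip93F (918), Eip63F-1 (827), the coactivator gene tai (695), the ETS factor gene Eip74EF (668) and gce, which encodes a juvenile hormone receptor (377), and all of these from E23 on were bound in all 3 replicate lists. Weaker peaks lay at crol (281, in 2 replicate lists), Hr4 (249, in 2), Blimp-1 (230, in 0) and ftz-f1 (228, in 3). The 9 members with no promoter peak included br, Hr3, Hr39 and Eip78C, named after their values were seen.

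The fat body list had 10 of 17 genes bound (58.8%, 3.08-fold, Fisher's exact adjusted p = 0.00195; 56.9% ± 3.40 over replicate lists, n = 3). Its strongest promoter peaks were at Lpin (signal 4076), the lipase gene bmm (1088), the fatty acid synthase gene FASN1 (958) and Apoltp (610). The 7 that were not bound were Fbp1, Fbp2, Lsp1alpha, Lsp1beta, Lsp1gamma, Lsp2 and the lipid carrier gene apolpp, named after their values were seen. The circadian clock list had 6 of 10 bound (60.0%, 3.15-fold, Fisher's exact adjusted p = 0.0189, 63.3% ± 5.77, n = 3), led by sgg (3753), cry (1829), Pdp1 (998) and vri (855). Its members that were not bound were Clk, cwo, cyc and tim, also named after their values were seen. Of the chromatin and insulator genes 13 of 30 were bound (43.3%, 2.27-fold, Fisher's exact adjusted p = 0.00985; 45.6% ± 5.09, n = 3). They were led by the Polycomb group genes ph-p (5087) and E(z) (2505), the remodeller gene brm (3619) and the insulator gene Cp190 (3054). Of the cytoplasmic ribosomal protein genes 35 of 86 were bound (40.7%, 2.13-fold, Fisher's exact adjusted p = 3.02e-05; 44.2% ± 9.93, n = 3), led by RpL34b (1433), RpL32 (1177), RpL23 (992) and RpS27 (836, in 2 replicate lists).

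Chemoreceptor genes were almost never bound, 2 of 179 (1.12%, 0.0586-fold, Fisher's exact adjusted p = 1.10e-12; 0.745% ± 0.323, n = 3), namely Gr77a (signal 287) and Ir67c (231, in 1 replicate list). Of the epidermis and cuticle genes 3 of 122 were bound (2.46%, 0.129-fold, Fisher's exact adjusted p = 6.14e-07; 2.46% ± 0.820, n = 3). These were Cpr50Ca (1557), Cpr66Cb (473, in 2 replicate lists) and Acp65Aa (278, in 2). Of the male accessory gland list 2 of 48 were bound (4.17%, 0.219-fold, Fisher's exact adjusted p = 0.0189; 3.47% ± 1.20, n = 3), Sfp26Ad (520) and again Acp65Aa, an adult cuticle protein gene that its symbol also placed in this list. With only the optimal peaks supported by both replicates 1 and 2, 4 lists passed in place of 8. The ribosomal (1.52-fold), chromatin (2.18-fold), fat body (2.70-fold) and accessory gland (0.273-fold) lists no longer did. The ribosomal list also did not pass with the peaks supported by both replicates 2 and 3 (1.54-fold). These sets hold 9371 and 9112 of the 11665 peaks called on all 3 replicates, so no replicate's reads were removed. With a distance of 200 bp the ecdysone list (2.35-fold) no longer passed and the circadian list, with 1 gene bound, was at 0.900-fold, and the strongest 50% of peaks ended the ribosomal (1.26-fold), fat body (2.73-fold) and accessory gland (0.161-fold) calls. The accessory gland list also did not pass with genes within 5 kb counted once (0.283-fold, Fisher's exact adjusted p = 0.114), nor the circadian list with gene bodies (2.16-fold, Fisher's exact adjusted p = 0.0576).

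**Figure D3:**
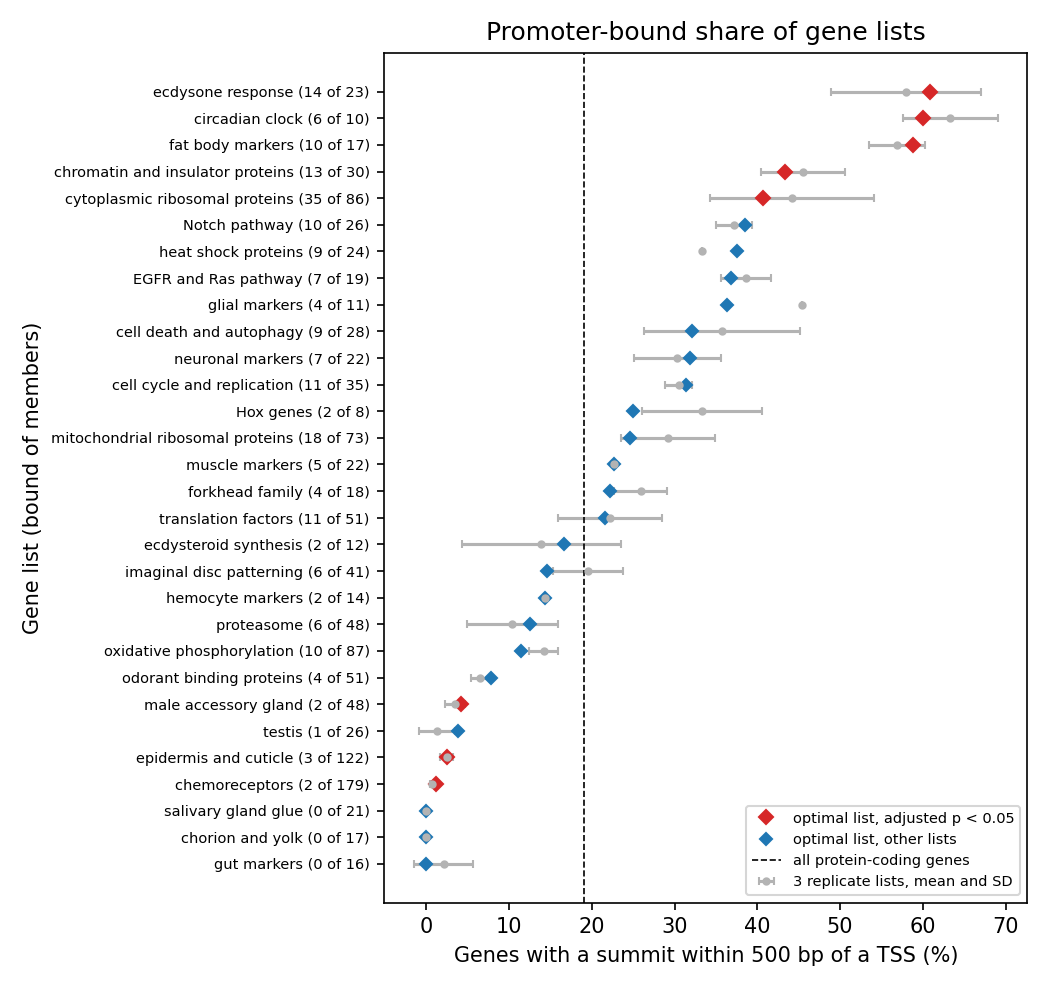
Percent of each list's genes with a summit within 500 bp of a TSS (diamonds, optimal list; red for the 8 lists at an adjusted p under 0.05) with the mean and SD of the 3 replicate lists (grey). The dashed line is the share of all protein-coding genes, 19.1%, and the ecdysone response list is highest at 60.9%.

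The other 22 lists did not pass. The forkhead family had 4 of 18 genes bound, CHES-1-like (signal 2509), foxo (1231), FoxK (885) and fkh (557), each in all 3 replicate lists (1.17-fold, Fisher's exact adjusted p = 0.818). Signalling lists lay above the background, with 10 of 26 Notch pathway genes (2.02-fold, Fisher's exact adjusted p = 0.0667) and 7 of 19 EGFR and Ras pathway genes (1.93-fold, Fisher's exact adjusted p = 0.133), as did heat shock proteins with 9 of 24 (1.97-fold, Fisher's exact adjusted p = 0.0909). The bound members numbered 2 of 8 Hox genes, 6 of 41 imaginal disc patterning genes, 2 of 12 ecdysteroid synthesis genes, 11 of 35 cell cycle and replication genes and 9 of 28 cell death and autophagy genes. Among tissue markers they were 7 of 22 for neurons, 4 of 11 for glia, 5 of 22 for muscle, 2 of 14 for hemocytes and 1 of 26 for testis. For housekeeping complexes they were 18 of 73 mitochondrial ribosomal proteins, 6 of 48 proteasome genes, 10 of 87 oxidative phosphorylation genes and 11 of 51 translation factors, and 4 of 51 odorant binding protein genes were bound. Salivary gland glue genes (0 of 21), gut markers (0 of 16) and chorion and yolk genes (0 of 17) had none. An approximate upper limit, 3 over the number of genes and not a Wilson interval, allows shares of up to 14.3%, 18.8% and 17.6%.

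Summits were poor in G and C. In the windows of 101 bp around the summits the mean GC content was 32.9%, against 43.7% in the flanks 500 bp away, a difference of -10.8 percentage points (replicate lists -10.5 ± 0.938, SD, n = 3). The summit had the lower GC content in 9251 of 11665 pairs (79.3%, Wilson interval 78.6 to 80.0%) and the higher in 2199. With flanks 1000 bp away, which had a mean of 41.3%, the difference was smaller, -8.50 percentage points. The dip was narrow, with 32.5% in the 51 bp at the summit, 45.1% at 300 bp upstream and 45.5% at 300 bp downstream in genome orientation, and 42.2% over all 6 arms. It was deepest at the strongest peaks, from 29.6% in the strongest 10% of peaks to 36.2% in the weakest 10%. At promoter-proximal peaks the summit stood at 34.0% against 44.4% in the flanks, and at other peaks at 32.5% against 43.3%. This comparison was added after the data were seen.

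**Figure D4:**
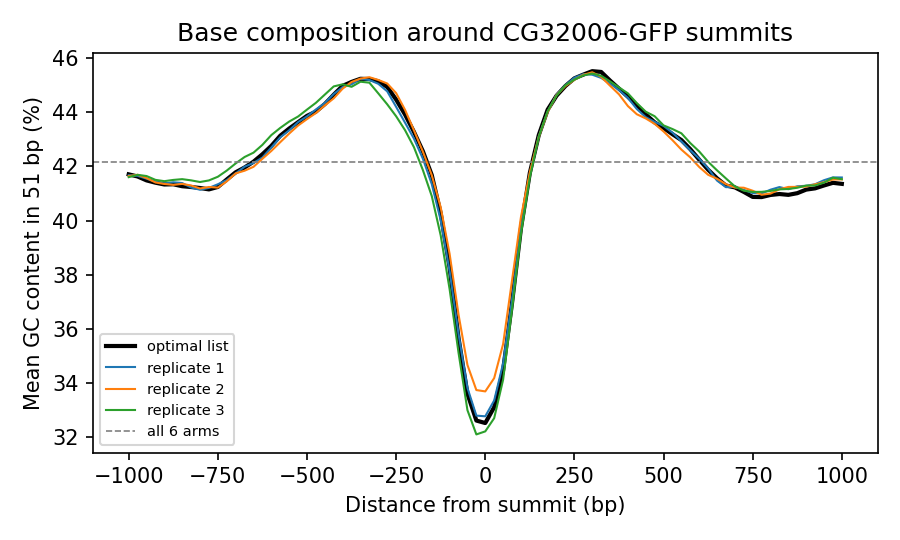
Mean GC content (percent, in 51 bp) by distance from the summit (bp) for the optimal list (black) and the 3 replicate lists (coloured), with the mean of all 6 arms (dashed, 42.2%). All 4 lines dip at the summit, to 32.5% in the optimal list.

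The sequence motif of forkhead factors was only slightly more frequent at summits. The core TRTTKRY was present in 40.3% of summit windows and 32.7% of flanks (1.23-fold, exact McNemar adjusted p = 8.91e-33), with 1.22-fold ± 0.0149 (SD, n = 3) over replicate lists. Against dinucleotide-shuffled summit windows, which keep the base composition, it was 1.07-fold (exact McNemar adjusted p = 5.91e-05). The stricter TGTTTAC was found in 2.23% of summits and 2.13% of flanks (1.05-fold, exact McNemar adjusted p = 0.653). Of 21 motifs, 6 were more frequent at summits than in flanks and 10 less frequent. Only the forkhead core and the BEAF-32 motif TCGATA (1.19-fold, exact McNemar adjusted p = 0.0183) were more frequent against both controls, the latter 1.26-fold against shuffled windows (exact McNemar adjusted p = 0.00191). The BEAF-32 excess over flanks did not pass in the strongest 50% of peaks (1.22-fold) or in promoter-proximal peaks (1.19-fold).

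The choice of control turned the direction of 7 motifs that passed against both. The homeodomain motif TAATTA was 1.76-fold against flanks and 0.819-fold against shuffled windows. In the other direction, motifs went from below to above 1, the GAGA factor motif from 0.440 to 2.39, the CA repeat from 0.340 to 4.03, Adf1 from 0.258 to 1.86, CAGCTG from 0.518 to 1.59, Su(H) from 0.752 to 1.46 and CTCF from 0.538 to 1.29. Flank windows were not compared with shuffled flanks. The values above 1 for these motifs were therefore not shown to be particular to summits. The TCF motif CTTTGAA was 2.06-fold against flanks (exact McNemar adjusted p = 9.89e-16) and 1.06-fold against shuffled windows (exact McNemar adjusted p = 0.499). GATA (1.5-fold) and STAT (1.23-fold) likewise passed only against flanks. The ecdysone receptor palindrome was found in 3 summit windows without a match in their flank and in 3 flanks without one at their summit.

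**Figure D5:**
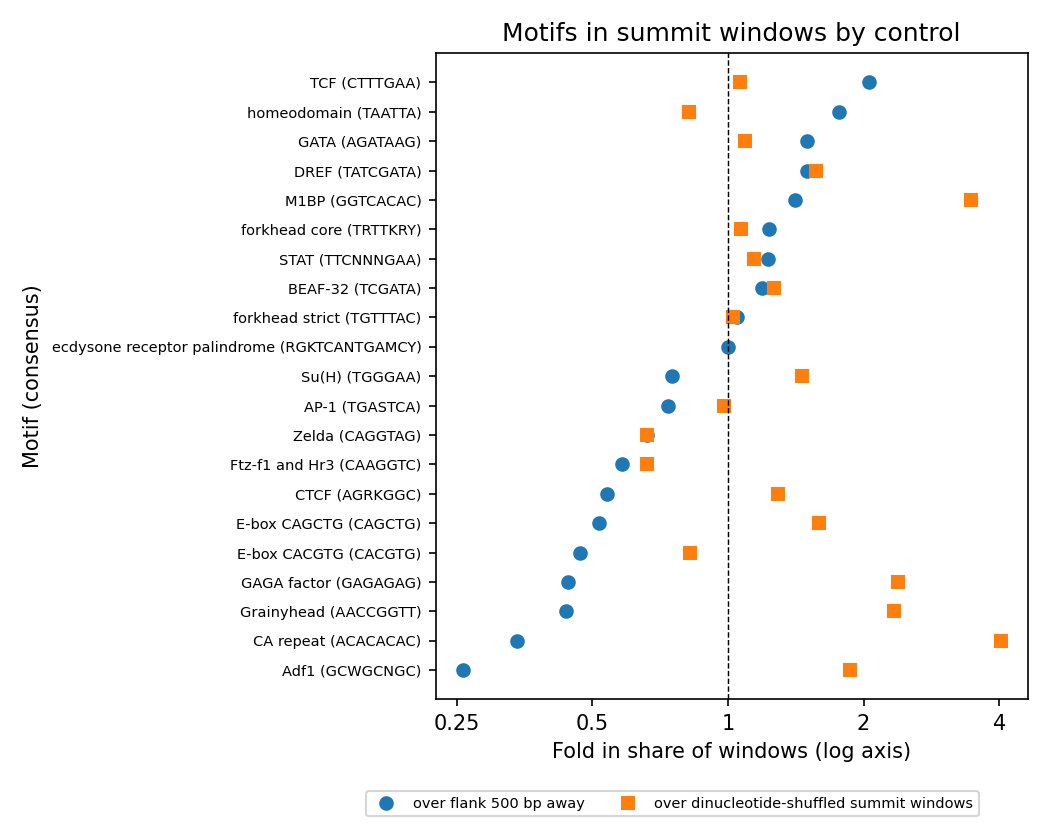
Fold in the share of windows with each of 21 motifs (log axis) at summits over flanks 500 bp away (blue circles) and over dinucleotide-shuffled summit windows (orange squares, none for the ecdysone receptor palindrome, which no shuffled window held). The homeodomain motif moves from 1.76 to 0.819 and the GAGA factor motif from 0.440 to 2.39.

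Against flanks 1754 of 8192 7-mers were more frequent at summits and 3775 less frequent, and all 64 words made of A and T only were among the more frequent. The 5 most frequent of these were AAATAAA (16.5% of summit windows, 1.68-fold), AAAATAT (16.3%, 2.66-fold), AAAAATA (16.2%, 2.02-fold), AAAAAAT (15.9%, 1.96-fold) and AAAATAA (1.92-fold). Their folds over replicate lists had SDs from 0.110 to 0.320 (n = 3). Against shuffled windows 594 words were more frequent and 620 less frequent, and 24 of the 64 A and T words were among the more frequent. Of the 5, AAAATAT fell to 1.52-fold (exact McNemar adjusted p = 1.51e-34), AAATAAA to 1.24, AAAAATA to 1.23 and AAAATAA to 1.15, all of which still passed, and AAAAAAT turned to 0.901-fold (exact McNemar adjusted p = 0.00193).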

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

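Alternatives for GC content and for coding-exon and intron shares were chosen after the data were seen; the others were planned. The peak count was 11625 in dm3, 10498 with overlapping peaks merged and 8581 with support by all 3 replicates. The promoter share, signal difference, GC difference and the arms 2R, 3L, X and 4 kept their direction and side of the threshold under every alternative run. Support by all 3 replicates, 73.6% in the main setting, was 78.3% with any overlap, 56.9% with a reciprocal overlap of 50%, 90.5% with replicate lists of 2N peaks, 76.6% for the strongest 50% of every list, and 78.1 to 81.5% when 1 replicate was left out, which needs support by fewer lists. Arm 3R no longer passed for the strongest 50% of peaks (0.970) and replicate 2's list (0.973), and arm 2L passed with genes as the denominator (0.937). The number of gene lists passing was 8 in the main setting and 5 for the strongest 50% of peaks. With the optimal peaks supported by both other replicates when 1 was left out it was 4 to 8. It was 13 in replicate 3's own list, 15 within 1000 bp and 16 with gene bodies. The cause was not tested. For single lists 11 alternatives ended a call, as did 200 bp for the circadian list (1 gene bound, 0.900-fold, Fisher's exact adjusted p = 1). For single motifs 25 alternatives ended a call. Over its alternatives the adjusted p of the ribosomal list ran from 5.29e-10 to 0.401. In promoter-proximal peaks 3 motifs were higher and 4 lower than flanks, with fewer windows tested. Against shuffled windows 1 motif was lower, and 594 7-mers were higher and 620 lower. Under that control GAGA factor (2.39), CTCF (1.29), CAGCTG (1.59), homeodomain (0.819), Su(H) (1.46), Adf1 (1.86), CA repeat (4.03) and AAAAAAT (0.901) reversed, and Grainyhead (2.33, exact McNemar adjusted p = 0.173) changed side of 1 without passing; it removes base composition by construction. The arm test was not run in dm3, for which arm lengths were not used here. Read depth is unknown, so its limit cannot be given.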

Other observations

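Other groups held strong promoter peaks without passing as lists, and some of their members are named here after their values were seen. In the EGFR pathway the ligand genes spi (signal 4276) and Krn (1174), the inhibitor gene aos (3140) and the repressor gene aop (1244) were bound in all 3 replicate lists. Notch pathway peaks were led by E(spl)m3-HLH (3168), numb (2338), mam (1673) and neur (1668). Small heat shock genes of 1 cluster on 3L were bound together, Hsp27 (7634), Hsp26 (1818) and Hsp22 (1433). Among cell death genes hid had a signal of 2403, and among neuronal genes elav had 3418, followed by Nrx-1 with 824. Higher signals than that of elav lay at eIF4EHP (6428) and eIF6 (4944) among translation factors. The same held for mRpS10 (5930) and mRpL41 (5883) among mitochondrial ribosomal proteins.

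Summits were scarcer in coding exons than their GC content predicted, and the cause was not tested. In windows of 101 bp with a coding centre, whose mean GC content was 52.5% against 40.0% elsewhere, 55 summits were found, where non-coding windows of equal GC content predicted 1023. Background regions of the pooled list, ranked below the optimal peaks, also had few summits in coding exons, 1.83% where shuffling placed 14.0%, and the share was 0.249% in the optimal list and 0.0857% in its strongest 50%. Of words with G or C, CAGTGCA (3.25% of summits, 2.05-fold over flanks, 3.64-fold over shuffled windows) and ACAGTGG (2.14%, 1.57-fold and 4.46-fold) had the lowest p-values against shuffled windows, chosen after the values were seen.

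The tests below were added after the patterns had been seen, and those by peak strength, of the bins with the highest GC content and of chromosome 4 were also written after their values were known. No biological explanation of the AT-rich summits, of chromosome 4 or of the gene lists was tested, since the design has 1 group, and a mock pull-down was not analysed here.

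The AT-rich summits remained in every subset tested. Without soft-masked bases the GC difference was -9.86 percentage points (SE 0.322, 1291 pairs) and without coding bases -10.0 (SE 0.126, 10471 pairs), which argues against repeats and against avoidance of exons as the whole cause, and the difference of the strongest 10% of peaks minus that of the weakest 10% was -7.00 points (SE 0.556), which argues against background peaks. In 500 bp bins ranked by GC content, summit density was 0.735 of the genome mean in the lowest 10%. It was highest at 38.9% GC (1.49) and fell to 0.146 in the highest 10%. Density thus did not simply grow with AT content at that scale. The bins are wider than the dip and take in its GC-richer sides, so they cannot decide on an AT bias at the summits. Among bins without coding bases the density was 0.552 in the lowest 10%, 1.32 at 41.1% GC and 0.523 in the highest 10%. This leaves a loss of GC-rich fragments open as a contribution. A preference of the protein, or of open chromatin, for short AT-rich stretches may also account for the dip, and the files do not separate these.

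The scarcity of peaks on chromosome 4 was not accounted for by GC content or by soft-masked bases, the only sequence properties tested. From the GC content of its bins 124 summits were predicted and 4 were found, and over bases that are not soft-masked the ratio of observed to expected was 0.0382. Background regions of the pooled list were as scarce, with 2 of 18335 on chromosome 4, a ratio of 0.0108. Below the N strongest peaks of replicates 1, 2 and 3 there were 14, 1 and 31 on it, ratios of 0.0758, 0.00542 and 0.168, so the replicates differed widely and all lay far below 1. A cause in the control alignment or the caller, such as a high control signal on this chromosome, may therefore contribute, and the lack of peaks at CG32006 cannot be read as a lack of binding.

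Genes with many TSSs have more chances of a nearby summit, so 8 lists were compared with genes matched on the number of TSSs (10000 draws, permutation p adjusted over the 8 lists). Matched genes were bound in 24.8% ± 4.39 (SD of draws) for the ribosomal list (40.7% bound, permutation adjusted p = 0.00373), 23.7% ± 7.28 for the chromatin list (43.3%, permutation adjusted p = 0.0333) and 31.1% ± 10.3 for the fat body list (58.8%, permutation adjusted p = 0.0333), which argues against TSS number as the whole cause. For the ecdysone list the matched share was 39.5% ± 9.36 (60.9% bound), and the permutation p of 0.0392 became 0.0523 after adjustment, so that TSS number stays open for it. For the circadian list the matched share was 35.3% ± 12.9 (60.0% bound, permutation adjusted p = 0.132), and TSS number may account for much of its excess. The chemoreceptor and cuticle lists lay below matched genes (permutation adjusted p = 0.0008 for each, from the smallest p the draws can give), and the accessory gland list did not pass (permutation adjusted p = 0.0562).

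Because FoxJ1 factors control cilia genes in vertebrates, a list of 39 matched cilia and intraflagellar transport genes was tested as a hypothesis written after the other lists had been seen and before its own value was. Of these 8 were bound (20.5%, 1.08-fold, Fisher's exact p = 0.838), which is no detectable excess over the background of 19.1%. The bound members were Rfx, Oseg1, Oseg6, IFT52, Kap3, Klp64D, BBS8 and Mks1.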
